A study of Mus musculus with 2 samples.

How the data were processed

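Libraries of single cells from tissue labelled olfactory epithelium of 2 male wildtype C57BL/6J mice were analysed, 1 library per mouse. Per the labels' protocols, the tissue was taken after decapitation, digested with enzymes at 37 °C, passed through a 40 µm sieve and treated with erythrocyte lysis solution, and libraries were made in droplets on the BMKMANU DG1000 platform. STAR, without a version, Cell Ranger 7.0.0 and the GRCm39 genome are named per the submitters' processing notes, which give neither the role nor the order of the tools. The annotation release is not given in the sources used here. The deposited tables hold counts per gene and barcode for 56953 genes, without normalization, and were taken as UMI counts, which the notes do not state. The names of 52029 gene identifiers were also looked up in a GRCm38 annotation, used only for older names and for overlaps of genes; no coordinates are given.

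The tables list 575908 barcodes for mouse 1, of which 530639 have a count, and 610731 for mouse 2, of which 584247 have a count, so cells were called here. Barcodes with at least 1000 UMIs numbered 14369 and 10017 and held 79.0% and 79.9% of the UMIs; 14301 and 9913 of them had at least 300 genes, and 14136 and 9680 at most 15% mitochondrial UMIs. Scrublet, run in scanpy 1.11.5, called 559 doublets in mouse 1 (3.95%) and 0 in mouse 2; since the latter is under the accepted 0.5%, the barcodes with the highest scores were removed there at 0.8% per 1000 cells, 750 in all (7.75%). The same rate would take 11.3% in mouse 1, so doublets may be left there. The cells left, 13577 and 8930, held 71744785 and 63115241 UMIs, with median mitochondrial shares of 4.16% and 4.84%. At these depths 3 UMIs, taken as the floor for a level, are 0.0418 and 0.0475 CPM, and 3 cells are 0.0221% and 0.0336% of cells. Barcodes of at most 50 UMIs (444292 and 491758, with 3.96% and 5.15% of the UMIs) were summed as a measure of free RNA, and those of 100 to 999 UMIs (60925 and 46548) as a check on the cell filter.

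Genes were split by a hash of the identifier, with marker genes always in the part used for clustering (27226 genes) and the members of the fixed lists, odorant and trace amine receptors, ribosomal, respiratory chain and mitochondrial genes always in the held-out part (29727 genes). Clustering used the 2000 most variable genes of its part, counts scaled to 10000 per cell, 30 principal components, 15 neighbours and Leiden at resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, Python 3.11.15), over both mice together, and gave 29 clusters. A cluster was named from 31 lists of 5 marker genes (155 symbols) if the list's mean log2 level over the other clusters, with 10 CPM added, was at least 1.5 and led the next list by 0.25, if 3 markers were detected in at least 10% of cells, and if its 10 leading genes did not speak for another class. The marker lists, the fixed lists, the filters, the test methods and the alternatives were chosen before the data were examined. Some tests of explanations, named in the last part, were chosen after the results were seen. The naming thresholds, the genes that bar a name and the comparisons were chosen after the clusters were seen and before any test between them, as none of the 9 planned comparisons could be made. Of 304 list symbols 302 were matched. Receptor genes numbered 1413, of which 257 are named as pseudogenes, and 16 trace amine receptor genes were counted apart. Shares have 95% Clopper-Pearson intervals and cluster levels 95% Poisson intervals (scipy 1.17.1).

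For tests, counts were summed per mouse and class, or per mouse and cluster, for those with at least 20 cells in both mice. All such sums entered one fit: 10 classes, 20 sums and 9 residual degrees of freedom with 13345 genes, and 24 clusters, 48 sums and 23 residual degrees of freedom with 17004 genes. Held-out genes that passed edgeR's filterByExpr, 6854 and 8715, were tested with edgeR 4.0.16 (TMM, robust quasi-likelihood F test) in R 4.3.3, with the mouse as a block because the classes of a mouse come from the same animal. Benjamini-Hochberg adjustment was made over the tested genes of each comparison, with 0.05 as the threshold. Holding genes out of the clustering lessens, and does not remove, the effect of testing groups that the same cells defined. Of 18 fixed gene lists and 3 groups (ribosomal protein, respiratory chain and mitochondrial genome genes), those with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg adjustment), and again with the correlation estimated. Named genes are, per comparison, those with an adjusted p under 0.05 and at least 50 CPM in one class, the 10 with the largest change in each direction, and up to 4 members of each list. Folds of a single mouse used log2 of CPM plus 1.

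Alternatives were 500 UMIs with 200 genes, 2000 UMIs, mitochondrial limits of 10% and 25%, doublets kept, resolutions of 0.5 and 2, each mouse clustered on its own, DESeq2 1.42.0 size factors or its Wald test, no block, no filter on low counts, the compared classes alone in the fit and sums thinned to one total. The tests were tested on simulated data with 100 genes changed 4-fold and 100 changed 2-fold. There every class had the mean profile of the second class compared, with a common dispersion and no effect of the mouse. Only genes above a minimum level in that class were changed. Between 83% (pericyte or smooth muscle-like and macrophage-like cells) and 100% of the former and between 15% and 53% of the latter were found, with 1 to 11 false calls. The share of 2-fold changes found was 22% for bone or cartilage-like against fibroblast-like cells, the largest classes. In the data the classes and the mice differ from each other, so these rates may not carry over. Of the libraries no test between the mice was made, since each is the only one of its mouse.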

Results

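Single-cell transcriptomes were collected from tissue labelled olfactory epithelium of 2 male C57BL/6J mice without a genetic change. Each library came from its own animal, as the labels name them mouse 1 and mouse 2, and both belong to 1 group. The series concerns the cell landscape of the olfactory epithelium, so the first question was which cell types the libraries hold. No treatment or genotype was compared, and every difference between the mice is a difference between 2 libraries. The tables held 95844802 UMIs over 575908 barcodes in mouse 1 and 86049057 UMIs over 610731 barcodes in mouse 2. After filtering, 13577 cells of mouse 1 and 8930 cells of mouse 2 remained, with medians of 3890 and 5234.5 UMIs and of 1731 and 1983 genes per cell. The intervals and floors below cover counting error only.

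Connective tissue cells made up most of both libraries. Fibroblast-like cells, named from Col1a1, Col1a2, Dcn, Pdgfra and Lum, were 37.7% of the cells of mouse 1 (95% Clopper-Pearson interval 36.9% to 38.5%) and 44.6% of those of mouse 2 (43.6% to 45.7%). Bone or cartilage-like cells, named from Bglap, Ibsp, Runx2, Col2a1 and Acan, were 38.4% (37.6% to 39.2%) and 30.4% (29.5% to 31.4%). Endothelial-like cells reached 2.46% in mouse 1 and 3.33% in mouse 2, pericyte or smooth muscle-like cells 1.33% and 1.79%, and macrophage-like cells 1.201% and 1.915%. T or NK-like cells were 1.48% and 0.739%, mast-like cells 0.597% and 0.392%, monocyte-like cells 0.457% and 0.325%, B-like cells 0.125% and 0.459%, and skeletal muscle-like cells 0.766% and 0.246%. Neutrophil-like cells showed the largest ratio among the classes higher in mouse 1, at 1.51% (1.31% to 1.73%) against 0.269% (0.172% to 0.400%). Clusters without a name held 13.9% and 15.5% of the cells; among them cluster 19, with 191 cells in mouse 1 and 6 in mouse 2, had markers of endothelial and cartilage cells and a median doublet score of 0.156. The thresholds that keep clusters unnamed were set after the clusters were seen. Of the bone or cartilage-like cells, cluster 1 (3100 cells) and cluster 5 (1670 cells) passed the limit of 1.5 at 1.66 each. Cluster 7 stood at 1.22 for that list and stayed unnamed. Names were rebuilt from markers and carry that uncertainty. With other cell filters, resolutions or treatment of doublets, the mean share of bone or cartilage-like cells moved from 34.4% to as low as 20.6% (each mouse clustered on its own), where unnamed clusters held 25.6%.

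**Figure D1:**
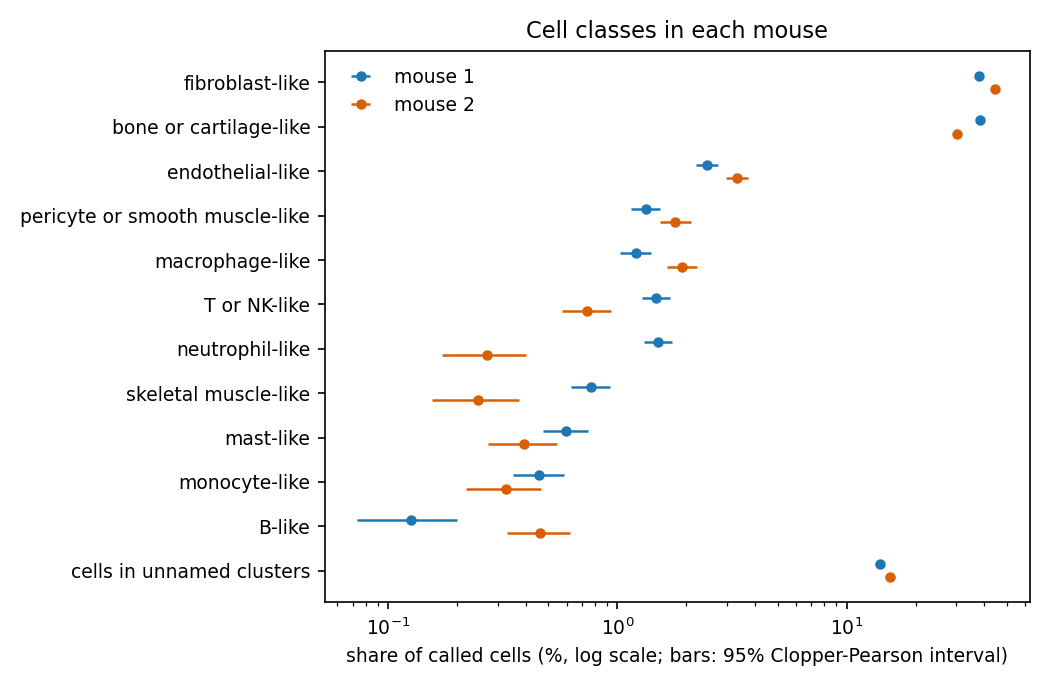
Share of called cells (percent, log axis) in each class for mouse 1 and mouse 2, with 95% Clopper-Pearson intervals as bars. Fibroblast-like and bone or cartilage-like cells lie above 30% in both mice, and neutrophil-like cells lie at 1.51% in mouse 1 and 0.269% in mouse 2.

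No cluster met the markers of an olfactory neuron, a sustentacular cell, a Bowman gland cell, a microvillar cell or an olfactory ensheathing cell, in these clusters or under any of the other cell filters and resolutions tried. The mature olfactory neuron markers Omp, Carns1, Stoml3, Umodl1 and Rtp1 together reached 3.36 CPM in the cells of mouse 1 and 4.07 CPM in those of mouse 2 (mean 3.72 ± 0.504, SD, n = 2). Barcodes of at most 50 UMIs, which hold free RNA, gave 4.21 and 4.51 CPM for the same genes. Omp, the olfactory marker protein gene (ENSMUSG00000074006), had 18 UMIs in mouse 1 and 42 in mouse 2, or 0.251 and 0.665 CPM against 0.790 and 1.35 CPM in those near-empty barcodes. Cyp2g1, an enzyme of sustentacular cells, had 6 and 5 UMIs, and Neurod1, a factor of neuronal precursors, had 0 in both mice, below the floor of 0.0418 and 0.0475 CPM that 3 UMIs set. Cells with UMIs of at least 3 mature olfactory neuron markers numbered 0 of 13577 and 1 of 8930, or at most 0.0272% and 0.0624% of cells with that detection. The share of neurons in which 3 markers would be detected was not measured. For sustentacular markers the counts were 0 and 0. They were 75 and 80 for the immature neuron list, 59 and 74 for the ensheathing glia list and 78 and 44 for the vomeronasal list. The horizontal basal list gave 18 and 9 cells, the globose basal list 6 and 9, and every other olfactory or respiratory list at most 1 per mouse. What kinds of cells these were was not tested. Cluster 26, with 39 and 35 cells, held 4 of the 5 horizontal basal markers, with Krt15 at 1575, Krt5 at 919 and Krt14 at 904 CPM, and its list stood 5.06 above the other clusters on the log2 scale. It was left unnamed because Krt13 and Krt7, keratins of other epithelia, were among its leading genes, a rule set after the clusters were seen. Clusters 16 and 23 were closest to the ensheathing glia list, with 2 of 5 markers detected in each, under the 3 that a name needs. Cluster 20 (160 and 14 cells) was closest to the microvillar ionocyte list, at 1.72 on the log2 scale, and also had 2 markers detected. Other lists were carried by genes with wide expression: the immature neuron list stood at 130 and 121 CPM, of which Dpysl3 gave 99.1 and 85.6, and the Bowman gland list at 964 and 762 CPM, of which Sox9, also a cartilage factor, gave 957 and 754. The immediate precursor list gave 2.63 and 2.19 CPM, the sustentacular list 1.199 and 2.060, the globose basal list 85.4 and 66.4, the horizontal basal list 38.4 and 21.7, the ciliated list 13.4 and 16.8 and the secretory list 1.78 and 4.09. The Trpm5 tuft list gave 20.7 and 25.9 CPM, the ionocyte list 161 and 52.2, the ensheathing glia list 299 and 396, the vomeronasal list 379 and 343, and the GC-D neuron list 7.99 and 8.25. The fibroblast list stood at 17848 and 18037 CPM and the bone or cartilage list at 4821 and 4768 CPM.

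**Figure D2:**
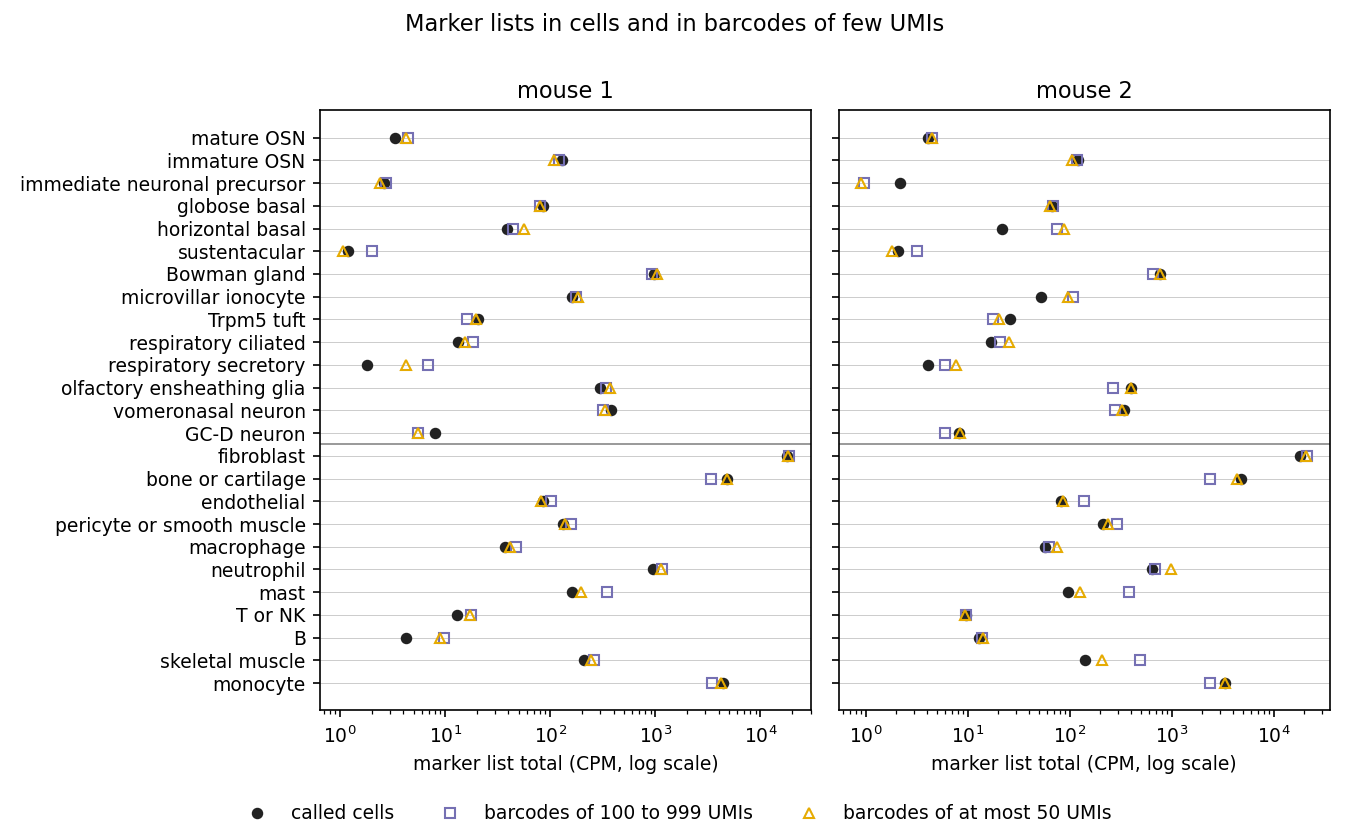
Summed level of each marker list (CPM, log axis) in called cells, in barcodes from 100 UMIs up to the cell filter and in barcodes of at most 50 UMIs, for each mouse; the grey line parts olfactory and respiratory lists from the others. The mature olfactory neuron list lies between 3.36 and 4.51 CPM in every kind of barcode of both mice.

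Of the signal transduction genes of olfactory neurons, those with wide expression were read and the channel subunits Cnga2 and Cnga4 were close to absent. Gnb1, a G protein subunit found in most cells, reached 187 CPM in mouse 1 and 147 CPM in mouse 2. Gnal, the olfactory G protein alpha subunit, stood at 10.2 and 11.1 CPM and Adcy3, the adenylyl cyclase of the pathway, at 12.5 and 13.2 CPM, both close to their levels of 12.1 and 13.3 and of 11.1 and 9.70 CPM in barcodes of at most 50 UMIs. The channel subunits Cnga2 and Cnga4 stood at 0.195 and 0.349 CPM and at 0.0836 and 0.0792 CPM. Among 9 matched symbols of the odorant binding and lipocalin list, Lcn11 had the most UMIs, at 11 in mouse 1 and 0 in mouse 2, too few for any test.

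Odorant receptor genes gave 9966 UMIs in mouse 1 and 7341 in mouse 2, or 139 and 116 CPM, against 121 and 102 CPM in barcodes of at most 50 UMIs. A single gene, Or5m3b (ENSMUSG00000045392), held 50.3% and 43.4% of them, and the 5 most abundant receptors 69.3% and 70.2%. Or5m3b stood at 69.9 and 50.4 CPM, Or7d10 at 12.1 and 18.2, Or8b53 at 5.56 and 6.00, Or2v1 at 6.27 and 4.82 and Or5p58 at 2.33 and 1.81 CPM. A receptor was dominant, with at least 3 UMIs and at least 2 times the next, in 612 cells of mouse 1 (4.51%, 4.16% to 4.87%) and 391 cells of mouse 2 (4.38%, 3.96% to 4.82%), of which 531 and 304 had Or5m3b. These cells belonged to no neuronal class. At least 1 UMI was found for 400 and 315 of the 1413 receptor genes, 219 of them in both mice. Across receptor genes, which are not independent replicates, the shares in the mice correlated with a Spearman rho of 0.580 and a Pearson r of 0.984, or 0.962 without Or5m3b. Trace amine receptors had 1 and 4 UMIs in total. Because no neuronal class was found, receptors per neuron and zones were not analysed here. Or2v1 overlaps Ifi47 and Or5p58 overlaps Gm44870 on the same strand in the GRCm38 annotation, so their counts are uncertain.

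The mice were compared within each class. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.984 in bone or cartilage-like, 0.981 in fibroblast-like, 0.901 in endothelial-like, 0.883 in macrophage-like and 0.806 in pericyte or smooth muscle-like cells. It was 0.766 in T or NK-like and 0.439 in neutrophil-like cells, and 3199 of 5856 genes were over 2-fold apart in the latter. Over 2-fold apart were 465 of 22646 genes in bone or cartilage-like, 420 of 19780 in fibroblast-like, 1264 of 11232 in endothelial-like, 1078 of 8404 in macrophage-like and 1720 of 9105 in pericyte or smooth muscle-like cells. The list of immediate early genes, which rise with tissue dissociation, stood at 12018 CPM in the endothelial-like cells of mouse 1 and 4855 CPM in those of mouse 2. In neutrophil-like cells it stood at 10243 and 2706 CPM, and in mast-like cells at 33903 and 37987 CPM. These are values of 2 libraries with no test.

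The planned comparisons between olfactory classes could not be made, so 8 comparisons between the classes and clusters found were set after the clusters were seen and before any test between them. All use genes held out of the clustering, counts summed per mouse and class, and edgeR's quasi-likelihood test with the mouse as a block and Benjamini-Hochberg adjustment, with n = 2 mice in every class. Values after ± are the SE of a log2 fold change or the SD of CPM over the mice. Directions per mouse come from the same counts as the calls, so agreement of the mice is no separate support. Genes with near-identical copies or pseudogenes, such as Ccl21a, Hspa1b and the ribosomal protein genes, may share reads, and their values are uncertain.

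Bone or cartilage-like cells were compared with fibroblast-like cells, the other abundant class. Among the genes with the largest change, higher in them were the cartilage matrix genes Chad (ENSMUSG00000039084) by 5.18 ± 1.04 on the log2 scale (1871 ± 708 against 52.7 ± 2.32 CPM), Col11a2 by 5.18 ± 0.71 (1376 ± 42.4 against 41.8 ± 13.7 CPM) and Comp by 4.93 ± 0.80 (2162 ± 294 against 77.4 ± 20.7 CPM). Clec3a, a lectin of cartilage, was higher by 6.10 ± 0.45. Lower were the complement gene C7 (−6.10 ± 0.45), the chemokine Ccl11 (−5.86 ± 0.67), the matrix genes Fbln2 (−5.78 ± 0.57) and Col14a1 (−5.69 ± 0.59) and the transcription factor genes Osr1 (−5.66 ± 0.44) and Ebf2 (−5.62 ± 0.51). Of 14 tested genes of cholesterol synthesis and uptake 11 were higher and none lower, and 11 also when adjusted over the list alone. Msmo1 was higher by 2.58 ± 0.34, Idi1 by 2.35 ± 0.36 and Cyp51 by 2.20 ± 0.35. The list's median was 1.499, positive in both mice, with a camera adjusted p = 3.82e-06, and adjusted p = 0.122 with an estimated correlation. Of 19 genes of xenobiotic metabolism 12 were lower and 2 higher, over all genes and adjusted over the list alone, with a median of −3.02, negative in both mice. Cyp1b1 was lower by −5.87 ± 0.70, Gstm2 by −4.40 ± 0.40 and Fmo2 by −4.26 ± 0.50, whereas the carbonyl reductase gene Cbr2 was higher by 4.19 ± 0.51. Its camera adjusted p = 1.92e-05, and adjusted p = 0.122 with an estimated correlation. Growth and survival factors moved both ways, with 2 higher and 7 lower of 16 (4 and 7 adjusted over the list alone). Lif was higher by 4.58 ± 0.59, and Cxcl12 (−4.97 ± 0.71), Il33 (−4.96 ± 0.49) and Bmp4 (−3.37 ± 0.46) were lower. Of 18 axon guidance genes 6 were higher and 6 lower, among them Sema3a (−4.00 ± 0.45) and Nrp1 (−3.48 ± 0.46). Of 15 regulators of receptor choice 4 were lower (5 adjusted over the list alone), among them Emx2 (−4.92 ± 0.47). Neither these nor the 15 other lists passed the camera test. In all, 1749 of 6854 genes passed, 830 higher and 919 lower, and all 1749 had the same direction in both mice. The count was 5769 of 11301 tested genes when these classes alone entered the fit and 2905 of 20264 without the filter on low counts.

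Endothelial-like cells were compared with fibroblast-like cells. Among the genes with the largest change, higher in them were the hyaluronan receptor gene Lyve1 (ENSMUSG00000030787; 8.94 ± 1.14, 1186 ± 263 against 2.42 ± 0.423 CPM), the receptor gene Tie1 (8.50 ± 0.65) and Sox18 (8.18 ± 0.50). The chemokine gene Ccl21a was higher by 9.04 ± 1.27 and Dtx1, a regulator of Notch signalling, by 8.75 ± 0.65. Lower were the collagen genes Col3a1 by −5.12 ± 0.65 (412 ± 198 against 12502 ± 369 CPM) and Col14a1 by −4.75 ± 0.58, the matrix gene Postn by −4.58 ± 0.62 and the methyltransferase gene Inmt by −5.45 ± 0.68. Of 12 Notch pathway genes 6 were higher and none lower (8 adjusted over the list alone), with Dll4 at 7.33 ± 0.58, Jag2 at 4.85 ± 0.64, Lfng at 4.82 ± 0.45 and Notch1 at 4.25 ± 0.41. The list's median was 2.38, positive in both mice, with a camera adjusted p = 1.26e-05, and adjusted p = 0.0137 with an estimated correlation. Of 16 growth and survival factors 8 were lower and none higher (10 adjusted over the list alone), among them Egfr (−4.23 ± 0.50), Il33 (−4.10 ± 0.56) and Cxcl14 (−3.21 ± 0.57). Their median was −1.96, or −1.72 with a member at 0 set to its bound, with a camera adjusted p = 5.68e-05, and adjusted p = 0.199 with an estimated correlation. Of 19 xenobiotic genes 9 were lower and 3 higher (11 and 3 adjusted over the list alone), with a median of −0.98, camera adjusted p = 0.0101, and adjusted p = 0.199 with an estimated correlation. Aldh1a1 was lower by −4.43 ± 0.57. Ribosomal protein genes had a median of −0.29 with 1 of 87 lower, Rpl39l (−4.15 ± 0.72), camera adjusted p = 5.03e-05, and adjusted p = 0.804 with an estimated correlation. These 3 medians were negative in both mice. Of 18 axon guidance genes 7 were higher and 2 lower, without a call for the list. Sema7a was higher by 5.67 ± 0.59 and Plxna4 by 5.35 ± 0.41. In all, 1215 genes passed, 617 higher and 598 lower, 1213 with the same direction in both mice. The count was 2530 of 9274 tested genes when these classes alone entered the fit. The endothelial-like class pooled clusters 12 and 18, which are compared below. Lyve1 (1640 against 8.67 CPM) and Ccl21a (4797 against 2.38 CPM) were far higher in cluster 12 than in cluster 18. Jag2 went the other way, at 5.13 CPM in cluster 12 against 72.2 CPM in cluster 18. Ccl21d was among the leading clustering genes of cluster 12, so Ccl21a, which may share its reads, was not independent of the clustering.

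Pericyte or smooth muscle-like cells were compared with fibroblast-like cells. Among the genes with the largest change, higher in them were Tinagl1 (ENSMUSG00000028776) by 9.14 ± 0.60 (492 ± 149 against 0.867 ± 0.458 CPM), the endothelin receptor gene Ednrb by 8.49 ± 1.00 and the calponin gene Cnn1 by 7.66 ± 0.48. Lower were Inmt (−4.92 ± 0.69), the protease gene Htra3 (−4.64 ± 0.61), the complement gene C3 (−4.63 ± 0.88), Ace (−4.60 ± 0.66) and the vessel receptor gene Tek (−4.45 ± 0.62). Of 87 ribosomal protein genes 31 were lower and none higher (71 adjusted over the list alone), with Rps12 at −1.53 ± 0.35, Rpsa at −1.51 ± 0.42 and Rps28 at −1.42 ± 0.34. The list's median was −0.995, negative in both mice, with a camera adjusted p = 4.77e-34, and adjusted p = 0.388 with an estimated correlation. Scaling by DESeq2's size factors moved all genes by 0.15 on the log2 scale; the ribosomal median was then −0.85 and 11 members were lower. Of 12 Notch pathway genes 4 were higher and none lower, with the same count adjusted over the list alone, among them the target gene Heyl (5.08 ± 0.61), Notch1 (2.54 ± 0.43) and Jag1 (2.35 ± 0.40). Their median was 1.39, positive in both mice, with a camera adjusted p = 0.00756, and adjusted p = 0.154 with an estimated correlation. Of 17 genes of the unfolded protein response 2 were lower and none higher (4 adjusted over the list alone), Atf5 (−2.05 ± 0.61) and Pdia6 (−1.42 ± 0.36), with a median of −0.70, negative in both mice, camera adjusted p = 0.00663, and adjusted p = 0.342 with an estimated correlation. Of the respiratory chain genes, 3 tissue-specific subunits were higher without a call for the list: Cox4i2 (5.31 ± 0.70), Ndufa4l2 (2.79 ± 0.42) and Cox6b2 (2.40 ± 0.50). In all, 746 genes passed, 385 higher and 361 lower, all with the same direction in both mice. The split was 429 higher and 277 lower with size factors, 302 and 198 without the mouse as a block, and 449 and 279 with mitochondrial UMIs up to 25%. The count was 1418 of 9300 tested genes when these classes alone entered the fit and 432 of 6624 with the sums thinned to one total.

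Macrophage-like cells were compared with fibroblast-like cells. Among the genes with the largest change, higher in them were the MHC class II genes Cd74 (ENSMUSG00000024610) by 10.24 ± 0.69 (18248 ± 1575 against 15.2 ± 1.69 CPM), H2-Ab1 by 10.04 ± 0.65 and H2-Aa by 9.95 ± 0.80 and the chemokine gene Ccl9 by 9.58 ± 1.22. Lower were the matrix gene Cilp (−5.02 ± 0.77), the splicing factor gene Nova1 (−4.91 ± 0.57), Ccl11 (−4.83 ± 0.77) and the Wnt modulator gene Sfrp2 (−4.70 ± 0.59). Of 13 genes of MHC class I presentation and interferon response 7 were higher and none lower (10 adjusted over the list alone), among them Isg15 (4.30 ± 0.65), the immunoproteasome genes Psmb8 (3.31 ± 0.38) and Psmb9 (3.15 ± 0.42) and the transporter gene Tap1 (1.96 ± 0.36). The list's median was 1.53, positive in both mice, with a camera adjusted p = 0.00038, and adjusted p = 0.175 with an estimated correlation. Of 15 regulators of receptor choice, which are also factors of connective tissue cells, 9 were lower and none higher (10 lower and 1 higher adjusted over the list alone), with Ebf1 at −3.74 ± 0.49 and Ebf2 at −3.42 ± 0.61. Their median was −2.20, or −1.60 with a member at 0 set to its bound, negative in both mice, with a camera adjusted p = 0.000113, and adjusted p = 0.0405 with an estimated correlation. The 4 zone genes, which share members with that list, had 3 lower, Nfib (−3.17 ± 0.64), Nfia (−2.38 ± 0.58) and Nfix (−2.20 ± 0.42), with a median of −2.29, camera adjusted p = 0.0131, and adjusted p = 0.435 with an estimated correlation. Growth and survival factors had 10 lower and 2 higher of 16 (11 and 2 adjusted over the list alone), Cxcl12 at −4.11 ± 0.75, with a median of −2.06, camera adjusted p = 0.0016, and adjusted p = 0.214 with an estimated correlation. Xenobiotic genes had 10 lower and 1 higher of 19 (12 and 2 adjusted over the list alone), Aldh3a1 at −4.12 ± 0.71, with a median of −2.38, camera adjusted p = 0.0026, and adjusted p = 0.175 with an estimated correlation. These 3 medians were negative in both mice. Cell cycle genes had 4 higher of 18 (5 adjusted over the list alone), among them Mki67 (3.88 ± 0.65), and cholesterol genes 4 higher of 14, with the same count adjusted over the list alone. Their medians of 1.46 and 0.90 were positive in both mice, with camera adjusted p = 0.047 and p = 0.0477, and adjusted p = 0.943 and p = 0.512 with an estimated correlation. Ribosomal protein and respiratory chain genes had medians of 0.23 and 0.34, positive in both mice, with camera adjusted p = 0.0407 and p = 0.0477, and adjusted p = 0.943 for both with an estimated correlation. Of the former 1 of 87 was lower, and of the latter 2 of 103 were higher and 1 lower. In all, 1574 genes passed, 767 higher and 807 lower, 1566 with the same direction in both mice. The balance depended on the settings, with 980 higher and 756 lower at resolution 2 and 720 and 799 with 500 UMIs. The calls of the last 4 lists were also lost under several other cell filters or scalings.

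**Figure D3:**
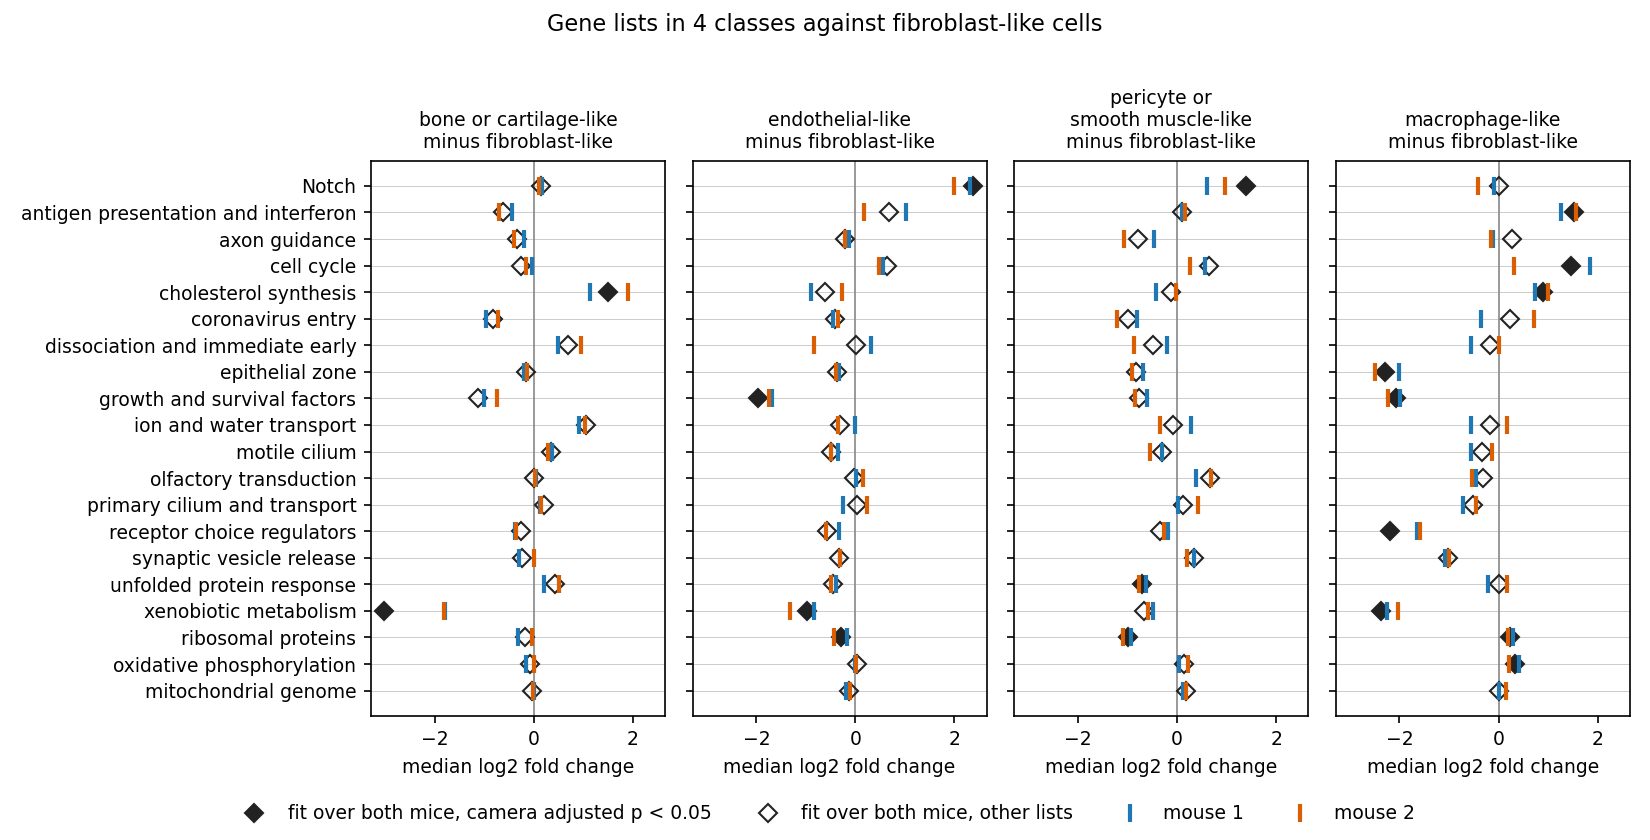
Median log2 fold change of each gene list (x axis) in 4 classes against fibroblast-like cells; diamonds are the fit over both mice, filled where the camera adjusted p is under 0.05, and the ticks are the medians of each mouse, on log2 of CPM plus 1. Notch pathway genes at 2.38 in endothelial-like cells and receptor choice regulators at −2.20 in macrophage-like cells are the only filled diamonds that stay under the threshold with an estimated correlation.

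The endothelial-like cells formed 2 clusters, cluster 12, led by Mmrn1, Reln and Flt4, and cluster 18, led by Flt1, Rgs5 and Cdh5. The list next to the endothelial one in cluster 18 was that of pericytes or smooth muscle, of which Rgs5 is a marker, at 2.87 above the other clusters on the log2 scale. Against cluster 18, the held-out gene Lyve1, a receptor of lymphatic endothelium, was higher in cluster 12 by 7.61 ± 0.71 (1640 ± 357 against 8.67 ± 6.13 CPM), the polarity gene Pard6g (ENSMUSG00000056214) by 6.44 ± 0.52 and the guidance cue gene Sema3a by 5.84 ± 0.69. Lower in cluster 12 were Sparcl1 (−6.37 ± 0.61), the semaphorin and VEGF co-receptor gene Nrp1 (−6.35 ± 0.56), the chemokine gene Cxcl12 (−5.56 ± 0.66), the Kit ligand gene Kitl (−4.35 ± 0.48) and the Notch ligand gene Jag2 (−3.73 ± 0.67). Of 13 genes of antigen presentation and interferon response 7 were lower and none higher (10 adjusted over the list alone), among them Irf7 (−3.62 ± 0.68), Ifit1 (−3.24 ± 0.82) and Psmb8 (−2.98 ± 0.64). The list's median was −1.59, negative in both mice, with a camera adjusted p = 1.37e-06, and adjusted p = 0.0717 with an estimated correlation. Of 102 respiratory chain genes 4 were higher and 3 lower, with the same counts adjusted over the list alone, the latter with Cox4i2 (−4.08 ± 0.87) and Ndufa4l2 (−3.73 ± 0.84), which were also higher in pericyte or smooth muscle-like than in fibroblast-like cells. The median was 0.48, positive in both mice, camera adjusted p = 1.37e-06, and adjusted p = 0.39 with an estimated correlation. Of 22 axon guidance genes 3 were higher and 6 lower (3 and 7 adjusted over the list alone), with a median of −0.38, and of 7 coronavirus entry genes Nrp1 alone passed (2 lower adjusted over the list alone), with a median of −0.95, or −0.35 with a member at 0 set to its bound. Both medians were negative in both mice, with camera adjusted p = 0.0412 for each, and adjusted p = 0.0717 and p = 0.319 with an estimated correlation. In all, 681 of 8715 genes passed, 296 higher and 385 lower, 674 with the same direction in both mice. DESeq2's Wald test called 237 higher and 556 lower, its size factors moved all genes by −0.13 on the log2 scale, and sums thinned to one total gave 433 of 8441 tested genes. With 2000 UMIs the split was 328 higher and 320 lower, and with doublets kept it was 336 and 338.

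Among bone or cartilage-like cells, cluster 5, led by Col10a1, a collagen of hypertrophic cartilage, was compared with cluster 3, led by Col2a1 and Ucma, with medians of 12151.5 and 10675 UMIs per cell. Higher in cluster 5 were the lipoxygenase gene Alox12 (ENSMUSG00000000320; 3.96 ± 0.46, 66.5 ± 8.21 against 4.22 ± 0.519 CPM), the ethanolamine kinase gene Etnk2 (3.55 ± 0.43), the sulfotransferase gene Chst5 (3.35 ± 0.41), the coagulation factor gene F5 (3.22 ± 0.48) and the homeobox gene Irx5 (2.89 ± 0.28). Lower were the matrix genes Col12a1 (−3.83 ± 0.60), Thbs1 (−2.83 ± 0.41) and Mfap2 (−2.68 ± 0.40) and the growth factor genes Bmp7 (−2.87 ± 0.44) and Igf1 (−2.58 ± 0.57). Those factors were the 2 members lower of 18 growth and survival factors, with none higher (3 lower adjusted over the list alone). The median was −0.29, camera adjusted p = 0.0291, and adjusted p = 0.24 with an estimated correlation. Of 13 genes of antigen presentation and interferon response 2 were lower and none higher (4 adjusted over the list alone), Ifit1 (−3.47 ± 0.82) and Ifit3 (−2.16 ± 0.55), with a median of −0.64, camera adjusted p = 0.000148, and adjusted p = 0.134 with an estimated correlation. Of 17 unfolded protein response genes Herpud1 (−1.11 ± 0.31) was lower (2 adjusted over the list alone), with a median of −0.40, camera adjusted p = 2.52e-05, and adjusted p = 0.0565 with an estimated correlation. None of 16 immediate early genes passed, with a median of −0.45, camera adjusted p = 0.00135, and adjusted p = 0.491 with an estimated correlation. The medians of mitochondrial genome (0.30, none of 28 past the threshold), respiratory chain (0.19, 1 of 102 higher, Cox4i2) and ribosomal protein genes (0.09, 1 of 89 higher, Rpl39l) were positive, with camera adjusted p = 2.54e-07, 4.06e-07 and 0.000294, and adjusted p = 0.107, 0.409 and 0.695 with an estimated correlation; counts adjusted over each list alone were the same. All these medians had the same sign in both mice. In all, 449 genes passed, 226 higher and 223 lower, all with the same direction in both mice. The count was 144 of 8715 tested genes without the mouse as a block, 2181 of 8893 when these clusters alone entered the fit and 216 of 9622 with each mouse clustered on its own.

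Cluster 1, led by Prg4, the lubricin gene of joint and cartilage surfaces, was compared with the same cluster 3, at medians of 4557 and 10675 UMIs per cell. Few held-out genes differed. Higher in cluster 1 were the growth factor gene Ptn (ENSMUSG00000029838; 2.67 ± 0.34, 106 ± 2.88 against 16.7 ± 0.352 CPM), Ifitm3, an interferon-induced membrane protein gene (2.21 ± 0.42), Sh2d4a (1.52 ± 0.34) and Rpl39l (1.37 ± 0.28). Lower were the matrix genes Spon1 (−2.20 ± 0.29, 41.5 ± 19.5 against 187 ± 33.7 CPM) and Matn3 (−2.08 ± 0.42). Of 89 ribosomal protein genes Rpl39l alone passed, also adjusted over the list alone, and the list's median was −0.23, negative in both mice, with a camera adjusted p = 3.22e-24, and adjusted p = 0.373 with an estimated correlation; it was 0.07 with each mouse clustered on its own. Unfolded protein response genes had a median of −0.31, negative in both mice, with none of 17 past the threshold (1 lower adjusted over the list alone), camera adjusted p = 1.22e-06, and adjusted p = 0.0201 with an estimated correlation. Immediate early genes and genes of antigen presentation and interferon response had medians of −0.66 and −0.44, negative in both mice, with none of 16 and none of 13 past the threshold (1 lower in each adjusted over the list alone), camera adjusted p = 1.65e-10 and p = 0.00155, and adjusted p = 0.348 for both with an estimated correlation. In all, 15 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9 higher and 6 lower, all with the same direction in both mice, and 572 had an unadjusted p under 0.05. The count and the balance depended on the settings, from 5 (3 higher and 2 lower) with each mouse clustered on its own to 184 (138 and 46) with doublets kept and 1258 (546 and 712) when these clusters alone entered the fit. The genes tested in these settings numbered 9622, 8769 and 8798. DESeq2's Wald test called 16 higher and 24 lower, and without the filter on low counts 42 were higher and 60 lower of 20597 tested genes.

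Among fibroblast-like cells, cluster 0, led by Ccl7, Tnfaip6 and Ptx3, was compared with cluster 4, led by Mfap5, at medians of 2583 and 5002 UMIs per cell. Among the genes with the largest change, higher in cluster 0 were the chemokine genes Cxcl1 (ENSMUSG00000029380) by 6.28 ± 0.99 (4309 ± 996 against 56.6 ± 18.5 CPM), Cxcl2 by 5.83 ± 1.25 and Cxcl10 by 4.82 ± 0.82 and the hyaluronan synthase gene Has1 by 5.05 ± 0.63. Of 16 immediate early genes 15 were higher and none lower (16 higher adjusted over the list alone), among them Btg2 (3.89 ± 0.51), Fosb (3.77 ± 0.57), Atf3 (3.58 ± 0.59) and Zfp36 (3.47 ± 0.48). The list's median was 2.81, positive in both mice, with a camera adjusted p = 1.6e-21, and adjusted p = 0.0385 with an estimated correlation. Lower in cluster 0 were the zinc finger gene Zc3h7a (−3.05 ± 0.40, 1797 ± 112 against 14808 ± 1526 CPM), the kinase-like gene Peak1 (−2.36 ± 0.32), the thioredoxin regulator gene Txnip (−2.19 ± 0.29) and the NADPH oxidase gene Nox4 (−1.96 ± 0.36). Of 9 ion and water transport genes 5 were higher and none lower, with the same count adjusted over the list alone, among them the bicarbonate transporter gene Slc4a4 (2.15 ± 0.27). The median was 0.86, positive in both mice, camera adjusted p = 0.00252, and adjusted p = 0.0385 with an estimated correlation. Of 17 unfolded protein response genes 5 were higher and none lower, with the same count adjusted over the list alone, among them Atf4 (1.81 ± 0.32) and the chaperone gene Hspa5 (1.71 ± 0.33), with a median of 0.42, camera adjusted p = 0.000813, and adjusted p = 0.08 with an estimated correlation. Of 102 respiratory chain genes 15 were lower and none higher (14 adjusted over the list alone), among them Sdhd (−1.11 ± 0.27), with a median of −0.33, camera adjusted p = 5.51e-09, and adjusted p = 0.27 with an estimated correlation. Ribosomal protein genes had a median of 0.38 with 2 of 89 higher (none adjusted over the list alone), and mitochondrial genome genes a median of 0.34 with none of 28 past the threshold, camera adjusted p = 7.89e-16 and p = 0.00252, and adjusted p = 0.334 and p = 0.278 with an estimated correlation. Primary cilium genes had 3 higher and 3 lower of 22 (3 and 5 adjusted over the list alone), with Kif17 (3.17 ± 0.59) higher and Bbs5 (−1.40 ± 0.47) lower, and a median of −0.76, camera adjusted p = 0.0386, and adjusted p = 0.27 with an estimated correlation. Antigen presentation genes had 2 of 13 higher and growth factors 5 of 18, with the same counts adjusted over each list alone. Their medians were 0.46 and 0.76 (0.52 with a member at 0 set to its bound), camera adjusted p = 0.0499 for both, and adjusted p = 0.414 and p = 0.27 with an estimated correlation. All these medians had the same sign in both mice. In all, 1561 genes passed, 898 higher and 663 lower, 1560 with the same direction in both mice. DESeq2's Wald test called 1085 higher and 1123 lower. The count was 762 of 8715 tested genes without the mouse as a block (533 higher and 229 lower). It was 3713 of 7982 when these clusters alone entered the fit and 623 of 9622 with each mouse clustered on its own (464 and 159).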

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

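The 8 comparisons tested in this part and the naming thresholds were chosen only after the clusters were seen, and the alternatives before the data were examined. Of the main values under an alternative, 282 stayed and 55 moved. A share, cell number or level moved when it left the main mean by more than the SD of the 2 mice. A count of genes or lists moved when it changed by more than 1.5 times. The number of olfactory clusters stayed only if unchanged. Of the other values, the list medians, 438 stayed, 72 weakened, 37 of them with the estimated correlation, and 1 reversed. A median weakened when it kept its sign but lost its camera call. These totals include each mouse left out, where shares and levels stay by construction and medians were checked for sign only. No olfactory class was named under any alternative, but no alternative dropped the rule that leaves the cluster with horizontal basal markers unnamed. For the values that moved, the cause was not tested unless stated. With mitochondrial UMIs up to 25%, mean shares were 24.6% for bone or cartilage-like (34.4% before), 46.8% for fibroblast-like (41.2%) and 19.0% for unnamed cells (14.7%), and cluster 1 against cluster 3 gave 64 genes (15). With doublets kept, bone or cartilage-like cells were 25.7%, endothelial-like 2.09% (2.89%) and unnamed 27.3%, with 184 genes and 7 lists (4) for cluster 1 against 3 and 7 lists (4) for endothelial-like cells. With each mouse clustered on its own, bone or cartilage-like cells were 20.6%, monocyte-like 0.188% (0.391%) and unnamed 25.6%; cartilage gave 5 lists (2), cluster 5 against 3 gave 216 genes (449), cluster 1 against 3 gave 5 and cluster 0 against 4 gave 623 (1561), and the ribosomal median of cluster 1 against 3 reversed to 0.0654 (−0.23). With 500 UMIs, endothelial-like cells were 3.58%, fibroblast-like 46.1%, monocyte-like 0.273% and unnamed 13.6%, and macrophage-like cells gave 5 lists (9). With 2000 UMIs unnamed cells were 13.2%, cartilage gave 4 lists and cluster 1 against 3 gave 75 genes; with 10% mitochondrial UMIs these were 11.2% for unnamed cells and 32 genes. At resolution 0.5 endothelial-like cells were 1.88%, monocyte-like 0% and unnamed 9.87%; at resolution 2 unnamed cells were 25.1%, and clusters 5 and 1 against 3 gave 299 and 7 genes. Without the low-count filter, which tests more genes, cartilage gave 2905 genes (1749) and cluster 1 against 3 gave 102. With the compared classes alone in the fit the number of tested genes also changed, to 11301 for cartilage (6854). The counts were then 5769 for cartilage, 2530 for endothelial-like (1215) and 1418 for pericyte or smooth muscle-like cells (746). They were 2181, 1258 and 3713 for clusters 5 against 3, 1 against 3 and 0 against 4. Without the mouse as a block these last 3 gave 144, 6 and 762. Thinned sums, which hold fewer counts, gave 432 for pericyte or smooth muscle-like cells and 433 for cluster 12 against 18 (681), and DESeq2's Wald test gave 40 for cluster 1 against 3. With an estimated correlation the called lists were 0 for cartilage (2), 1 for endothelial-like (4), 0 for pericyte or smooth muscle-like (3), 1 for macrophage-like (9), 0 for cluster 12 against 18 (4), 0 for 5 against 3 (7), 1 for 1 against 3 (4) and 2 for 0 against 4 (9). Not run, because no matching clusters were found, were clusters 5 and 1 against 3 at 500 UMIs and at resolution 0.5, cluster 0 against 4 at resolution 0.5, cluster 12 against 18 with each mouse on its own, and all receptor-per-neuron and zone analyses. With 2 mice, leaving out either gives only the other's value, which says nothing about stability, and classes of few cells limit what can be called.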

Other observations

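The tests of the frontonasal genes, of overlaps of the other 4 receptors, of free RNA for each of the 5 receptors and of the cell filter for neutrophil-like cells were chosen only after the results were seen. Cluster 26, with 39 cells in mouse 1 and 35 in mouse 2, held the highest levels of these genes: Ltf at 12189 CPM, Krt13 at 2955, Krt15 at 1575, Gsto1 at 15876, Gsta4 at 2183, Cbr2 at 1686, Cyp2a5 at 1257 and Cyp2f2 at 981 CPM. No other cluster had more than 1 keratin gene among its leading genes. Cluster 16 held the highest levels of the glial genes Prx (1612 CPM) and Sox10 (638 CPM) and of Carns1 (92.9 CPM), the last a mature olfactory neuron marker. Cluster 20, with 160 and 14 cells, had Coch at 7457, Tnmd at 1315 and Tbx3 at 980 CPM.

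Posterior Hox genes (19 genes) stood at 115 CPM in mouse 1 and 100 CPM in mouse 2 in endothelial-like cells, with 140 and 125 in cluster 12 and 48.7 and 33.1 in cluster 18. In fibroblast-like cells they stood at 0.815 and 0.612 CPM and in bone or cartilage-like cells at 0.504 and 0.330 CPM, but in skeletal muscle-like cells at 25.3 and 37.5 CPM, from 8 and 5 UMIs. Msx1 stood at 128 and 127 CPM in fibroblast-like cells, and Tbx5, a forelimb gene, at 0.349 and 0.245 CPM. The same 431 barcode sequences were called as cells in both libraries.

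The absence of olfactory neurons and sustentacular cells from libraries labelled olfactory epithelium was weighed first. The cell filter is excluded by its test, since the mature olfactory neuron markers reached at most 4.51 CPM in barcodes under the filter. Reep1, at 2.75 CPM over all cells, was counted where it is expressed (44.6 CPM in endothelial-like cells), and 54 of 55 marker and transduction genes had a UMI, but whether genes that only olfactory cells express were lost in counting stays open, as no cells that should hold them were found. Such a loss would not hide neurons: genes shared by all neurons (Snap25, Syt1, Stmn2 and Tubb3 together) were highest in cluster 12, at 135 and 184 CPM by mouse, under the 500 set. A trunk or limb origin with posterior Hox expression is excluded for fibroblast-like and bone or cartilage-like cells, with posterior Hox genes at most 0.815 CPM. An origin without such expression was not tested. Nor were the endothelial-like and skeletal muscle-like cells, where posterior Hox genes are higher. In unnamed cluster 8, closest to the fibroblast list, these genes stood at 4.19 and 5.38 CPM, from 8 and 9 UMIs. Alx1 and Pax3, genes of the frontonasal skeleton, were at 41.3 CPM or more in fibroblast-like and in bone or cartilage-like cells. This could come from nasal connective tissue taken without most of its epithelium, but the test cannot tell, as it was set after the values were seen. Keratin genes were among the leading genes of cluster 26 (39 and 35 cells), so epithelium was not wholly missing. Which epithelium these cells came from was not tested.

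Odorant receptor counts in non-neuronal clusters had a peak for Or5m3b in neutrophil-like cluster 17 (267 CPM, 236 to 301; 323 and 64.0 by mouse), for Or8b53 in mast-like cluster 22 (112 CPM, 81.2 to 151) and for Or2v1 in endothelial-like cluster 18 (173 CPM, 144 to 206). Free RNA spread alike over all cells is excluded for Or8b53 (lower bound 81.2 against a median cluster of 5.14 CPM) and Or2v1 (144 against 5.85 CPM), both past 3 times the median in each mouse. It cannot be told apart from own expression for Or5m3b, Or7d10 and Or5p58; the receptors were grouped by this outcome, so that 2 and 0 passed adds nothing to the levels. The peak of Or5m3b rests on mouse 1, with 64.0 CPM in mouse 2 near the median cluster (52.7 CPM), and the lower bounds of Or7d10 (32.2 against 16.5 CPM) and Or5p58 (2.18 against 2.15 CPM) were too low. Over all cells Or5m3b stood above its level in barcodes of at most 50 UMIs (69.9 and 50.4 against 42.6 and 25.7 CPM) and Or7d10 below (12.1 and 18.2 against 19.2 and 27.3 CPM); how far those barcodes match the free RNA in cells was not tested. Reads shared with Ifi47 could account for Or2v1, with a Spearman rho of 0.713 across 29 clusters, just past the 0.7 set. Of the other 4 receptors 1, Or5p58, overlaps another gene on its strand in the GRCm38 annotation and Or5m3b, Or7d10 and Or8b53 overlap none; the annotation used for the counts was not seen, so shared reads cannot be told apart from own expression there.

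Neutrophil-like cells were 5.62 times as frequent in mouse 1 as in mouse 2. More blood in the tissue of mouse 1 could account for it: haemoglobin in barcodes of at most 50 UMIs stood at 1201 against 435 CPM, a ratio of 2.76. An erythrocyte lysis step, per the labels' protocols, may alter that measure. It may also not be of blood alone. Hbb-bs was among the leading genes of cluster 19, with 191 cells in mouse 1 and 6 in mouse 2. In bone or cartilage-like cluster 1, with 17.0% and 8.89% of the cells, the erythroid list came next, at 1.22 on the log2 scale. Which cells the free haemoglobin RNA came from was not tested. The cell filter is excluded, as the ratio stayed at 5.03 with 500 and 5.01 with 2000 UMIs. Ngp, a gene of neutrophil precursors, had 117 UMIs in mouse 1 and 3904 in mouse 2, the opposite order to the shares. It was among the leading genes of neutrophil-like cells. There the precursor list stood 6.88 and the neutrophil list 7.47 above the other clusters on the log2 scale. With 205 and 24 cells, 3199 of 5856 genes were over 2-fold apart. Whether neutrophil-like cells were of the same kinds in both mice was not tested, so the ratio may not compare 1 cell type. No biological cause was tested, as both mice are of 1 group.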
